A study of Mus musculus with 13 samples.

How the data were processed

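Tumour RNA of 13 mouse liver tumour samples was analysed, 8 treated with luciferase siRNA nanoparticles (siLuc) and 5 with Yap siRNA nanoparticles (siYap), each for 9 days. Per the labels' protocols, libraries were made with the ScriptSeq Complete Gold kit, which removes ribosomal RNA, and were sequenced on a HiSeq2500. Per the submitters' processing notes, Trimmomatic 0.30, TopHat2 2.0.8, Cufflinks and Cuffdiff 2.1.1 were used with the mouse build mm10. The role of each tool, the gene annotation and the handling of reads that match several places are not given in the sources used here. Genes with near-identical copies, such as Saa1 and Saa2, Lyz1 and Lyz2 or the Cyp2c family, are therefore uncertain.

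The authors deposited 1 Cuffdiff table per library, with 23361 gene symbols. Per the file headers, it holds the raw fragments of each gene and its FPKM. The raw fragments are estimated counts that the authors deposited without scaling, since they are not always whole. Between 97.6% and 98.0% of values per library lay within 1e-06 of a whole number, and the totals differed between libraries. The deposited FPKM values are fragments per kilobase of transcript and sequencing depth, scaled by Cuffdiff. The replicate index in the siYap tables runs up to 7 with gaps, so the scaling may have used libraries that are not analysed here. Per the file headers, 3 genes (Alb, Apob and Trf) carried the mark that their depth was too high to estimate and were at 0 in all libraries, so they were left out. A further 21 genes, among them Itgam and Cd36, carried a failure mark in at least 1 library and were kept. A table of FPKM for the whole series was not used here.

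The estimated counts were rounded to whole numbers. Totals ran from 23637021 to 37043914 fragments per library. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3, robust, TMM normalization, edgeR's default filter on low counts by group, which left 15132 genes), siYap against siLuc over all 13 libraries with no covariates. P-values were adjusted by the Benjamini-Hochberg method and genes were called at an adjusted p under 0.05. All log2 fold changes and adjusted p of genes are from this test unless another is named, and levels are FPKM as mean ± SD over libraries, n = 8 for siLuc and n = 5 for siYap. The standard error is the fold change over the root of the F statistic.

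Before the data were examined, the groups, this design, the alternatives, 30 gene lists and a rule for named genes were fixed. The rule took Yap1, Wwtr1, Stk3 and Stk4, then the 12 largest rises and 12 largest falls among called genes with a mean of at least 1 FPKM in either group, the same sign and an unadjusted p under 0.05 in counts summed per file-name number, and the same sign without each library in turn, and then up to 4 members of each list with the smallest p. Names of the Rik or Gm kind were passed over. Ctgf, Nkd1, Nkd2, Znrf3, Tcf7, Fzd5, Arntl and Dbp fall outside this rule and were chosen after their values were seen. Some genes that the rule takes are not reported here. Lists were tested with camera in limma 3.58.1 on log2 CPM with a preset inter-gene correlation of 0.01, two-sided and adjusted over the 30 lists, then with an estimated correlation, and with fry. None of the 16 calls held with an estimated correlation, where unadjusted p was under 0.05 for 2 lists. Fry tests whether a list's genes move on balance one way and does not compare them with other genes. Counts within a list are given from adjustment over all genes and from adjustment over the list alone. The exact permutation tests of list means, over splits of the libraries, were added after seeing the data, as were exact permutations of the list means within the digits of the file code (252 splits) and 3 further lists (Wnt feedback, imprinted and clock genes).

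The file names carry a number that libraries of 1 group share, with 5 numbers in siLuc and 3 in siYap. It may be an animal, but the labels do not say. They also carry a code whose first digit (6, 7 or 8) splits the libraries into 3 groups, each with both treatments, which may be a batch. Alternatives were counts summed per number, limma-voom with the number as a random effect, the replicate number as a block, the digit as a term, sex as a term (called from Xist under 100 CPM and Y-linked genes), size factors of DESeq2 1.42.0, upper-quartile scaling, DESeq2's Wald test, no filter or a mean count of at least 50, limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with at least 1 FPKM in 5 libraries, each library left out in turn, and an adjusted p under 0.01 or a log2 fold change of at least 1. Leaving out siYap replicates 1 and 3 together, and siYap replicate 1 with siLuc replicate 8, was added after seeing the data. No pair of libraries within a group agreed within sampling noise (lowest chi-square per degree of freedom 34.8), which excludes only the same library sequenced again. All were counted as separate, as labelled, although some may share an animal.

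The gene test was tested on simulated data with the real genes' means and library sizes, 200 genes changed and 14955 genes tested. It recovered 10.4% of genes changed 1.5-fold, 50.7% of those changed 2-fold and 81.8% of those changed 4-fold, and called 4 of 14757 unchanged genes. The simulated counts were independent between libraries and between genes, and far fewer genes changed than were called in the real data. These rates therefore do not cover shared animals or batches. Coordinates are 1-based, from the GENCODE M21 annotation of the same build, and were matched by symbol. Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for permutations and plots.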

Results

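Tumour RNA was sequenced from mice that develop hepatocellular carcinoma, the main cancer of hepatocytes, after loss of the Hippo pathway kinases Mst1 and Mst2 in the liver. Mst1 (gene Stk4) was deleted in the germline and Mst2 (gene Stk3) was deleted by an adenovirus carrying Cre. Tumours were followed by ultrasound, and the animals were assigned at random to intravenous lipid nanoparticles carrying an siRNA against Yap, the transcriptional co-activator that the Hippo kinases restrain, or an siRNA against luciferase, which has no target in the mouse. Treatment lasted 9 days. The comparison asks what happens to the tumour transcriptome when Yap is lowered in a tumour that formed without its upstream kinases. There were 8 control libraries (siLuc) and 5 libraries from treated tumours (siYap). The replicate indices inside the siYap tables were 0, 1, 5, 6 and 7, so other siYap libraries may have been in the authors' run, and none with the missing indices was available. The estimated fragments assigned to genes ran from 23637021 to 37043914 per library. The lowest totals were those of siYap replicates 1 (23637021) and 3 (25801886). These libraries also had the highest levels of the ribosomal precursor Rn45s, at 1160 and 1882 CPM (counts scaled to the library total) against 479 to 812 CPM in the other 11 libraries. On the first principal component, which held 41.9% of the variance of log2 CPM, the siYap libraries lay between 52.1 and 89.03 and the siLuc libraries between -64.0 and -23.1. All libraries but one were female by their Xist and Y-linked fragments. siLuc replicate 8 was male, with 28874 fragments on 4 Y-linked genes against at most 11 in any other library. The labels do not say which libraries came from separate animals, so p-values measure the spread between these libraries.

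Yap1 transcript fell in every siYap library. Yap1 (mouse genome build mm10, chromosome 9, 7931999 to 8004596, minus strand) stood at 9.999 ± 1.37 FPKM (SD, n = 8) in siLuc and 3.29 ± 0.845 FPKM (SD, n = 5) in siYap tumours, which is 2.99-fold lower. Its highest siYap value, 4.17 FPKM, lay below its lowest siLuc value, 8.10 FPKM. The log2 fold change was -1.58 ± 0.17 (SE), with an adjusted p of 2.36e-05. A two-sided exact permutation test over the 1287 splits of the 13 libraries gave p = 0.000777, the smallest that it can give. Over the 56 splits of the 8 numbers found in the file names, which may be animals, the exact p was 0.0179, also the smallest possible. Within the 3 groups of libraries that share the first digit of their file code (6, 7 and 8), the Yap1 difference was -1.31, -1.97 and -1.63 on the log2 scale. Digit 8 holds only 1 library of each treatment, and its siLuc library is the male replicate 8. Differences within digit 8, here and below, thus compare single libraries. Wwtr1 (chromosome 3, 57455649 to 57575910), which encodes the Yap paralog Taz, was measured at 16.0 ± 4.199 FPKM in siLuc and 12.7 ± 2.70 FPKM in siYap, and the difference did not pass the test (log2 fold change -0.34 ± 0.19, adjusted p = 0.192). Stk4 was near zero throughout, at 0.053 ± 0.026 FPKM in siLuc and 0.044 ± 0.019 FPKM in siYap. Stk3 was read at 6.12 ± 0.619 and 5.22 ± 1.32 FPKM (log2 fold change -0.26 ± 0.13, adjusted p = 0.145), and the adjusted p was 0.0490 without siYap replicate 1. The value covers the whole gene and does not check the deletion of its floxed part.

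**Figure D1:**
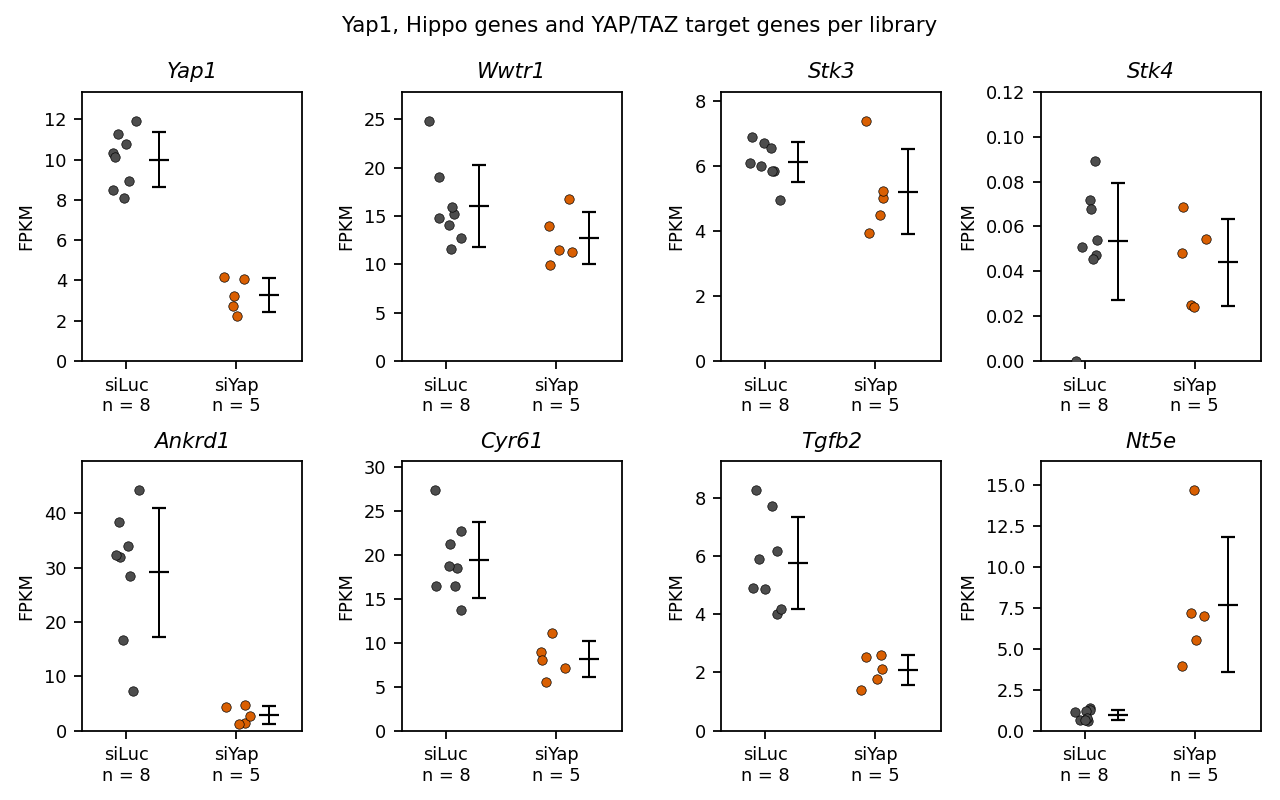
FPKM per library of Yap1, Wwtr1, Stk3, Stk4 and 4 members of the YAP/TAZ target list, with 8 siLuc libraries in grey and 5 siYap libraries in orange; bars give the mean and SD. Yap1, Ankrd1, Cyr61 and Tgfb2 lie lower in every siYap library than in any siLuc library, Nt5e lies higher, and Stk4 stays below 0.1 FPKM in all libraries.

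Established target genes of Yap and Taz moved in both directions in siYap tumours. Of the 21 tested members of the YAP/TAZ target list, 7 fell, 2 rose and 12 did not pass the test. With p-values adjusted over the list alone, 8 fell and 3 rose. Ankrd1, a muscle ankyrin repeat protein and common reporter of Yap activity, fell from 29.2 ± 11.9 to 2.89 ± 1.605 FPKM (log2 fold change -3.35 ± 0.47, adjusted p = 0.000205). Cyr61, a matricellular protein, fell from 19.4 ± 4.29 to 8.14 ± 2.05 FPKM (adjusted p = 0.000308), and Tgfb2, a TGF-beta ligand, fell from 5.76 ± 1.57 to 2.08 ± 0.511 FPKM (adjusted p = 9.10e-05). Nt5e, an ectonucleotidase, rose from 0.950 ± 0.324 to 7.68 ± 4.12 FPKM (log2 fold change 3.03 ± 0.28, adjusted p = 6.83e-06). Ctgf, chosen for mention after its values were seen, was at 16.98 ± 8.80 and 8.63 ± 1.39 FPKM and missed the threshold (adjusted p = 0.0533), but passed without siLuc replicate 1 (0.0333), 2 (0.0174) or 3 (0.0459). The list as a whole had a median log2 fold change of -0.63 and did not pass camera's test against other genes (adjusted p = 0.0702, and 0.539 with an estimated correlation). It passed when siLuc replicate 1 (adjusted p = 0.0364) or siYap replicate 3 (adjusted p = 0.0472) was left out, and in counts summed per file-name number (adjusted p = 0.0411). A two-sided exact permutation test of the mean of its members gave p = 0.00466 over the libraries (0.0127 adjusted over the 30 lists) and 0.0179 over the file-name numbers (0.0595 adjusted).

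Among components of the Hippo pathway itself, 5 of 26 tested genes fell and none rose, and the same 5 fell with adjustment over the list alone. Ajuba, a LIM-domain inhibitor of the Lats kinases, fell from 13.6 ± 2.33 to 4.04 ± 0.740 FPKM (log2 fold change -1.73 ± 0.15, adjusted p = 4.60e-06). Tead4, a DNA-binding partner of Yap, fell from 3.42 ± 0.936 to 0.810 ± 0.265 FPKM (adjusted p = 7.40e-05). Amot, the scaffold angiomotin, fell from 11.4 ± 2.33 to 5.78 ± 0.701 FPKM (adjusted p = 0.000629). Yap1 itself is a member of this list. The list was called lower by camera (adjusted p = 0.0477, and 0.539 with an estimated correlation), and the call ended when any one of siLuc replicates 2, 7 and 8 or siYap replicates 2, 4 and 5 was left out (adjusted p of 0.0580 to 0.0938), or with the digit of the file code (0.0533) or sex (0.0566) as a term.

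Across the transcriptome, 4668 of 15132 tested genes differed between siYap and siLuc tumours, 2422 higher and 2246 lower in siYap. All 5 siYap libraries lay above all 8 siLuc libraries for 957 genes, 6.32% of those tested, and below them for 883 genes, 5.84%. Chance gives 0.0777% in each direction if the 13 libraries are independent. It gives up to 1 in 56 if only the 8 file-name numbers are. With counts summed per file-name number, 5 siLuc against 3 siYap, 3793 genes were called, of which 3559 were among the 4668 with the same sign. With the number as a random effect in limma, 4693 genes were called. The correlation estimated within a number was -0.056, so this fit made no allowance for libraries that share an animal. Without siYap replicates 1 and 3 together, an alternative chosen after seeing the data, 2984 genes were called.

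**Figure D2:**
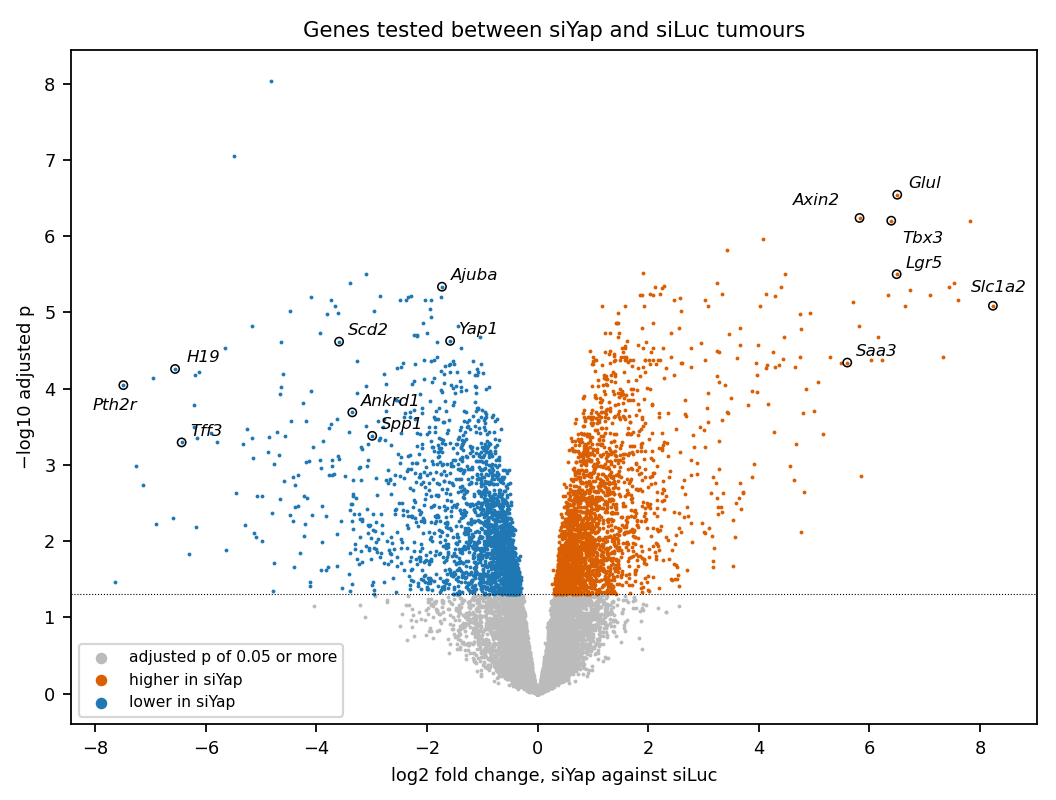
Log2 fold change of siYap against siLuc (x axis) against −log10 of the adjusted p (y axis) for the 15132 tested genes; orange points are higher and blue points lower in siYap at an adjusted p under 0.05, grey points are not called, and the dotted line marks 0.05. Of the labelled genes on the right, Glul, Axin2, Tbx3, Lgr5 and Slc1a2 belong to the pericentral list and Saa3 to the acute phase list.

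Of the 12 largest rises, 6 were in genes that, in normal liver, mark the hepatocytes around the central vein. Of the 21 pericentral genes tested, 18 rose and none fell, also with adjustment over the list alone, and the median log2 fold change was 4.47. Glul, glutamine synthetase (chromosome 1, 153899944 to 153909723), rose from 46.0 ± 16.4 FPKM in siLuc to 4147 ± 1910 FPKM in siYap (log2 fold change 6.51 ± 0.41, adjusted p = 2.86e-07). Slc1a2, a glutamate transporter, rose from 1.13 ± 1.55 to 390 ± 214 FPKM (log2 fold change 8.23 ± 0.75, adjusted p = 8.18e-06). Oat, ornithine aminotransferase, rose from 38.3 ± 45.7 to 2885 ± 1672 FPKM, and Rhbg, an ammonium transporter, from 0.403 ± 0.304 to 70.4 ± 47.0 FPKM. siLuc replicate 4 held the highest siLuc level of Slc1a2 (4.88 FPKM) and Oat (149.0 FPKM), and without it their log2 fold changes went from 8.23 to 9.08 and from 6.23 to 7.004. The list also holds direct targets of Wnt signalling. Axin2 (chromosome 11, 108920349 to 108950783) rose from 0.180 ± 0.093 to 10.2 ± 3.93 FPKM (log2 fold change 5.82 ± 0.38, adjusted p = 5.78e-07), Lgr5, an R-spondin receptor, from 0.118 ± 0.065 to 10.7 ± 5.94 FPKM, and Tbx3, a T-box repressor, from 0.160 ± 0.078 to 13.4 ± 4.05 FPKM. Gulo and Cyp1a2, a vitamin C synthesis enzyme and a caffeine-metabolizing cytochrome, rose 22.2-fold and 55.9-fold. The list was called higher by camera (adjusted p = 7.33e-17). With an estimated correlation its adjusted p was 0.362. Within the digits 6, 7 and 8 of the file code, the mean of its members differed by 4.61, 4.49 and 5.27 on the log2 scale.

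Outside the list, the secreted Wnt inhibitor Notum rose from 0.377 ± 0.320 to 30.4 ± 16.1 FPKM, the Wnt-responsive transcription factor Sp5 from 0.017 ± 0.018 to 2.02 ± 0.931 FPKM, and the phosphatase Lhpp from 1.33 ± 1.51 to 132 ± 62.3 FPKM, each with all siYap libraries above all siLuc libraries. The remaining genes among the 12 largest rises were AW549542 (0.081 ± 0.061 to 15.5 ± 10.01 FPKM), the orexin receptor Hcrtr2 (0.0098 ± 0.011 to 1.61 ± 1.54 FPKM) and the desmosomal protein Pkp1 (0.014 ± 0.016 to 1.92 ± 0.907 FPKM). siLuc libraries held at most 3 fragments of Hcrtr2 and 7 of Pkp1. The log2 fold change of Lhpp went from 6.65 to 7.36 without siLuc replicate 4, and that of Hcrtr2 from 7.33 to 6.75 without siYap replicate 4.

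Some of the genes that mark the periportal end of the lobule went the other way. Of 18 tested periportal genes, 7 fell and none rose, also with adjustment over the list alone, and the median log2 fold change was -1.15. Hsd17b13, a lipid droplet enzyme, fell from 505 ± 211 to 61.0 ± 57.8 FPKM (adjusted p = 0.000870), and Cyp2f2, a naphthalene-metabolizing cytochrome, fell from 147 ± 144 to 7.26 ± 10.5 FPKM (log2 fold change -4.43 ± 1.01, adjusted p = 0.00540). Without siYap replicate 1 their log2 fold changes went from -3.07 to -3.73 and from -4.43 to -5.68. The epithelial cadherin Cdh1 fell from 16.1 ± 5.46 to 4.34 ± 2.99 FPKM (adjusted p = 0.00461). Camera called the list lower (adjusted p = 0.000623, and 0.539 with an estimated correlation). The mean of the list lay between -2.74 and -0.16 in the siYap libraries relative to the siLuc mean, on the log2 scale, so that the spread between siYap libraries was wide. The highest of them, siYap replicate 1, lay within the range of the siLuc libraries (-0.35 to 0.55).

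**Figure D3:**
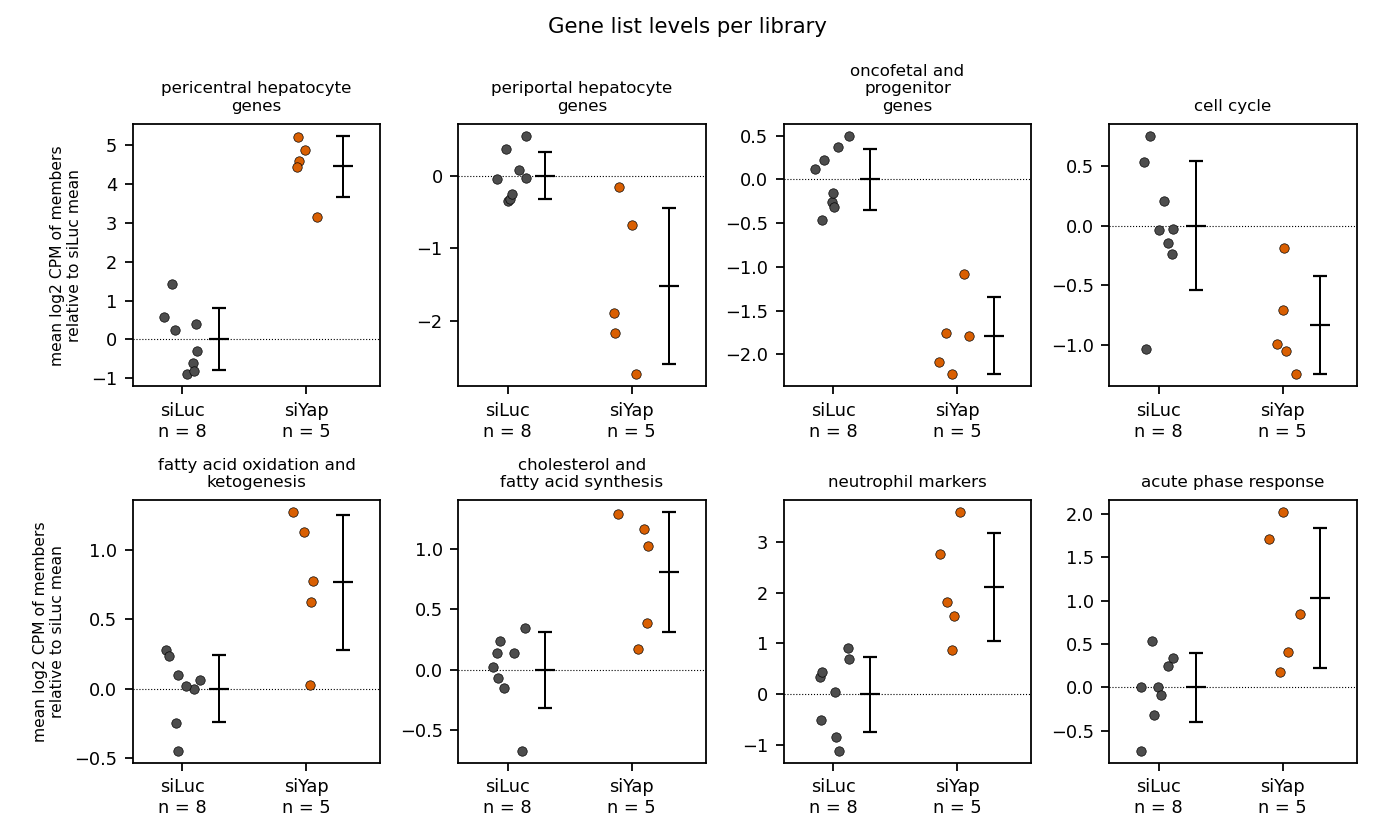
Mean log2 CPM of the members of 8 gene lists in each library, relative to the mean of the 8 siLuc libraries (dotted line); grey points are siLuc (n = 8), orange points siYap (n = 5), bars give mean and SD. The pericentral level lies between 3.15 and 5.21 in siYap libraries and at most at 1.42 in siLuc libraries.

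Most of the tested genes of fetal liver and of liver progenitors fell. In the oncofetal and progenitor list, 14 of 23 tested genes fell and none rose, and 15 fell when adjusted over the list alone. The median log2 fold change was -1.85. The imprinted long non-coding RNA H19 (chromosome 7, 142575529 to 142578143) fell from 2963 ± 1625 to 29.8 ± 21.6 FPKM (log2 fold change -6.55 ± 0.78, adjusted p = 5.52e-05). Scd2, the desaturase of fetal liver, fell from 54.6 ± 15.9 to 4.54 ± 3.30 FPKM (adjusted p = 2.42e-05). The transcription factor Sox4 fell from 9.44 ± 3.65 to 2.11 ± 0.969 FPKM, and Igf2bp3, an RNA-binding protein of embryonic tissues, fell from 4.94 ± 1.80 to 1.15 ± 0.257 FPKM. Camera called the list lower (adjusted p = 5.97e-06, and 0.362 with an estimated correlation). Markers of cholangiocytes, the cells of the bile duct, overlapped this list in several members. Of 21 tested, 7 fell and none rose, against 7 and 1 adjusted over the list alone. Spp1, osteopontin, fell from 4120 ± 1039 to 521 ± 421 FPKM (log2 fold change -2.99 ± 0.47, adjusted p = 0.000416), Pkhd1, fibrocystin, from 39.2 ± 13.7 to 10.9 ± 3.14 FPKM, and Epcam from 14.8 ± 9.28 to 3.23 ± 1.91 FPKM. The cholangiocyte list was called lower by camera (adjusted p = 0.0473, and 0.556 with an estimated correlation), a call that ended without any one of siLuc replicates 2, 3, 5, 6 and 7 or siYap replicates 2, 4 and 5 (adjusted p of 0.0555 to 0.110), in counts summed per file-name number (0.178) and with the digit of the file code as a term (0.0625). Its mean changed sign between digits of the file code, with differences of -0.27, -1.58 and 0.19. In the Notch list, 3 of 15 tested genes rose and 3 fell, also over the list alone. Camera did not call it (adjusted p = 0.872), and its median (0.04) and mean (-0.10) log2 fold change differed in sign. The Notch target Hes1 fell from 24.3 ± 11.8 to 8.91 ± 3.31 FPKM and the ligand Jag1 from 10.7 ± 2.69 to 5.21 ± 1.122 FPKM.

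The largest falls included H19 and a set of genes that belong to none of the lists. Tff3, a mucosal trefoil peptide, fell from 780 ± 556 to 8.24 ± 6.34 FPKM (log2 fold change -6.44 ± 1.02, adjusted p = 0.000507), and the prostate stem cell antigen Psca from 23.2 ± 18.97 to 0.251 ± 0.205 FPKM. The parathyroid hormone receptor Pth2r fell from 1.71 ± 1.497 to 0.0076 ± 0.011 FPKM, the synaptotagmin Syt17 from 2.48 ± 1.71 to 0.031 ± 0.039 FPKM, the kinase-like Styk1 from 5.65 ± 4.70 to 0.093 ± 0.081 FPKM, and Tmigd1 from 3.59 ± 4.07 to 0.063 ± 0.037 FPKM, each with every siYap library below every siLuc library. Ptgds, a prostaglandin D synthase, fell from 11.7 ± 16.7 to 0.140 ± 0.127 FPKM, with overlap between the groups. Prss37, Lipn and Olfr153 had at most 1 fragment in each siYap library, and Vmn2r3 at most 4. Their siLuc means were 1.68, 2.41, 1.04 and 2.31 FPKM, but their lowest siLuc libraries held 0, 1, 1 and 4 fragments. The groups overlapped for each of these genes and for Tff3. Without siYap replicate 1, the log2 fold change went from -6.44 to -7.09 for Tff3, from -6.16 to -7.08 for Psca, from -6.12 to -7.15 for Syt17, from -6.18 to -7.05 for Ptgds and from -7.13 to -8.26 for Vmn2r3. It went from -6.18 to -5.33 for Ptgds without siLuc replicate 4, from -7.49 to -8.45 for Pth2r without siYap replicate 5, from -5.79 to -5.11 for Tmigd1 without siLuc replicate 8, and from -7.26 to -8.74 for Prss37 and from -6.21 to -7.69 for Olfr153 without siYap replicate 3. With the file-name number as a random effect, the calls of Ptgds (adjusted p = 0.153), Lipn (0.150) and Vmn2r3 (0.0632) ended.

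Of the 7 lists fixed for hepatocyte function, camera called 4 higher at its preset correlation and none at an estimated one, and chance cannot be excluded for that number. Among hepatocyte transcription factors, 11 of 25 tested genes rose and none fell, also over the list alone. Nfia rose from 3.91 ± 0.444 to 10.8 ± 5.16 FPKM, the retinoid X receptor Rxra from 29.1 ± 3.39 to 56.6 ± 12.6 FPKM and Onecut2 from 8.72 ± 1.86 to 16.4 ± 3.51 FPKM. In the bile acid list, 10 of 22 rose and 2 fell, against 10 and 3 adjusted over the list alone. Slco1b2, a hepatic uptake transporter, rose from 179 ± 105 to 1935 ± 949 FPKM and Hsd3b7 from 50.0 ± 12.3 to 164 ± 67.0 FPKM, while Akr1d1, the delta4-3-oxosteroid reductase of bile acid synthesis, fell from 168 ± 33.3 to 60.8 ± 13.3 FPKM. In the xenobiotic list, 15 of 39 rose and 5 fell, also over the list alone. Por, the electron donor of microsomal cytochromes, rose from 27.9 ± 8.61 to 167 ± 77.3 FPKM, Fmo1 from 47.2 ± 17.2 to 178 ± 47.6 FPKM, and Cyp2c38, a member of a gene family with near-identical copies, from 2.20 ± 1.58 to 60.2 ± 21.4 FPKM. In the fatty acid oxidation list, 13 of 31 rose and none fell, and 17 rose when adjusted over the list alone. The peroxisomal thiolase Acaa1a rose from 14.5 ± 2.20 to 32.9 ± 9.19 FPKM, Etfa from 103 ± 17.8 to 204 ± 52.4 FPKM and the acyl-CoA synthetase Acsl1 from 66.2 ± 14.1 to 166 ± 60.3 FPKM. Camera called these lists higher with adjusted p of 0.00861, 0.00633, 0.00171 and 3.80e-05, in the order given. With an estimated correlation the adjusted p were 0.539, 0.539, 0.556 and 0.539. The xenobiotic, bile acid and amino acid lists share members with the pericentral list.

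The other 3 hepatocyte lists were not called. Of 33 genes of the urea cycle and amino acid catabolism, 14 rose and 6 fell, against 15 and 6 adjusted over the list alone. Prodh, proline dehydrogenase, rose from 29.2 ± 9.94 to 249 ± 122 FPKM, Tat, tyrosine aminotransferase, from 140 ± 36.4 to 409 ± 29.9 FPKM, and Bckdhb from 26.0 ± 4.11 to 59.3 ± 9.95 FPKM. The list had adjusted p = 0.0702 in camera, and passed when siLuc replicate 4 (adjusted p = 0.0153) or siYap replicate 3 (adjusted p = 0.0263) was left out. Of 20 glucose and glycogen genes, 2 rose and 3 fell, also over the list alone (camera adjusted p = 0.872). The hepatocyte glucose transporter Slc2a2 fell from 248 ± 45.5 to 102 ± 29.2 FPKM, and Ppp1r3c, a glycogen-targeting phosphatase subunit, rose from 4.11 ± 3.88 to 20.5 ± 6.69 FPKM. Of 35 plasma protein genes, 5 rose and 5 fell, also over the list alone (camera adjusted p = 0.370). Coagulation factor F5 and the retinol carrier Rbp4 rose 2.51-fold and 2.15-fold, and Serpinf2 and the complement component C9 fell 2.60-fold and 2.85-fold. Alb, Apob and Trf carry no value in the files used here and were left out.

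Genes of cholesterol and fatty acid synthesis rose, 16 of 29 tested, and none fell. The count adjusted over the list alone was 19. The median log2 fold change was 0.81. The sterol reductase Dhcr7 rose from 3.82 ± 0.700 to 8.97 ± 4.01 FPKM (log2 fold change 1.27 ± 0.22, adjusted p = 0.000745), and mevalonate kinase Mvk from 8.43 ± 1.34 to 19.98 ± 10.6 FPKM. Camera called the list higher (adjusted p = 1.38e-05, and 0.539 with an estimated correlation). In the list of glycolysis and hypoxia genes, 3 of 25 rose and none fell, 2 over the list alone, and the list was not called (adjusted p = 0.292). Egln3, a prolyl hydroxylase, rose from 2.69 ± 0.793 to 11.7 ± 5.72 FPKM.

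Many cell cycle genes were lower in siYap tumours. Of 38 tested, 19 fell and none rose, and 21 fell when adjusted over the list alone. The median log2 fold change was -0.82. Cdc20, an activator of the anaphase-promoting complex, fell from 3.77 ± 1.21 to 0.935 ± 0.193 FPKM (log2 fold change -1.94 ± 0.27, adjusted p = 0.000144), the kinesin Kif20a from 5.35 ± 2.15 to 1.401 ± 0.372 FPKM, cyclin Ccne1 from 3.70 ± 1.42 to 1.05 ± 0.435 FPKM, and Cdk1 from 7.08 ± 2.79 to 1.98 ± 0.943 FPKM. Camera called the list lower (adjusted p = 1.50e-06, and 0.539 with an estimated correlation). A two-sided exact permutation test of the mean of its members gave p = 0.0194 over the libraries (0.0416 adjusted over the 30 lists) and 0.0179 over the file-name numbers (0.0595 adjusted). The difference was -0.30, -1.07 and -1.58 within the digits of the file code. An exact permutation within the digits gave p = 0.0357 (0.0714 adjusted). It takes libraries that share a file-name number as independent, although within each digit all siYap libraries carry the same number. Among apoptosis genes and p53 targets, 4 of 20 rose and 7 fell, also over the list alone, and the list was not called (adjusted p = 0.235). The anti-apoptotic Bcl2l1 rose from 6.19 ± 0.659 to 12.2 ± 2.63 FPKM and the pro-apoptotic Bcl2l11 from 3.32 ± 0.380 to 7.94 ± 3.04 FPKM. The p53 target Phlda3 fell from 5.23 ± 2.20 to 1.10 ± 0.338 FPKM.

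**Figure D4:**
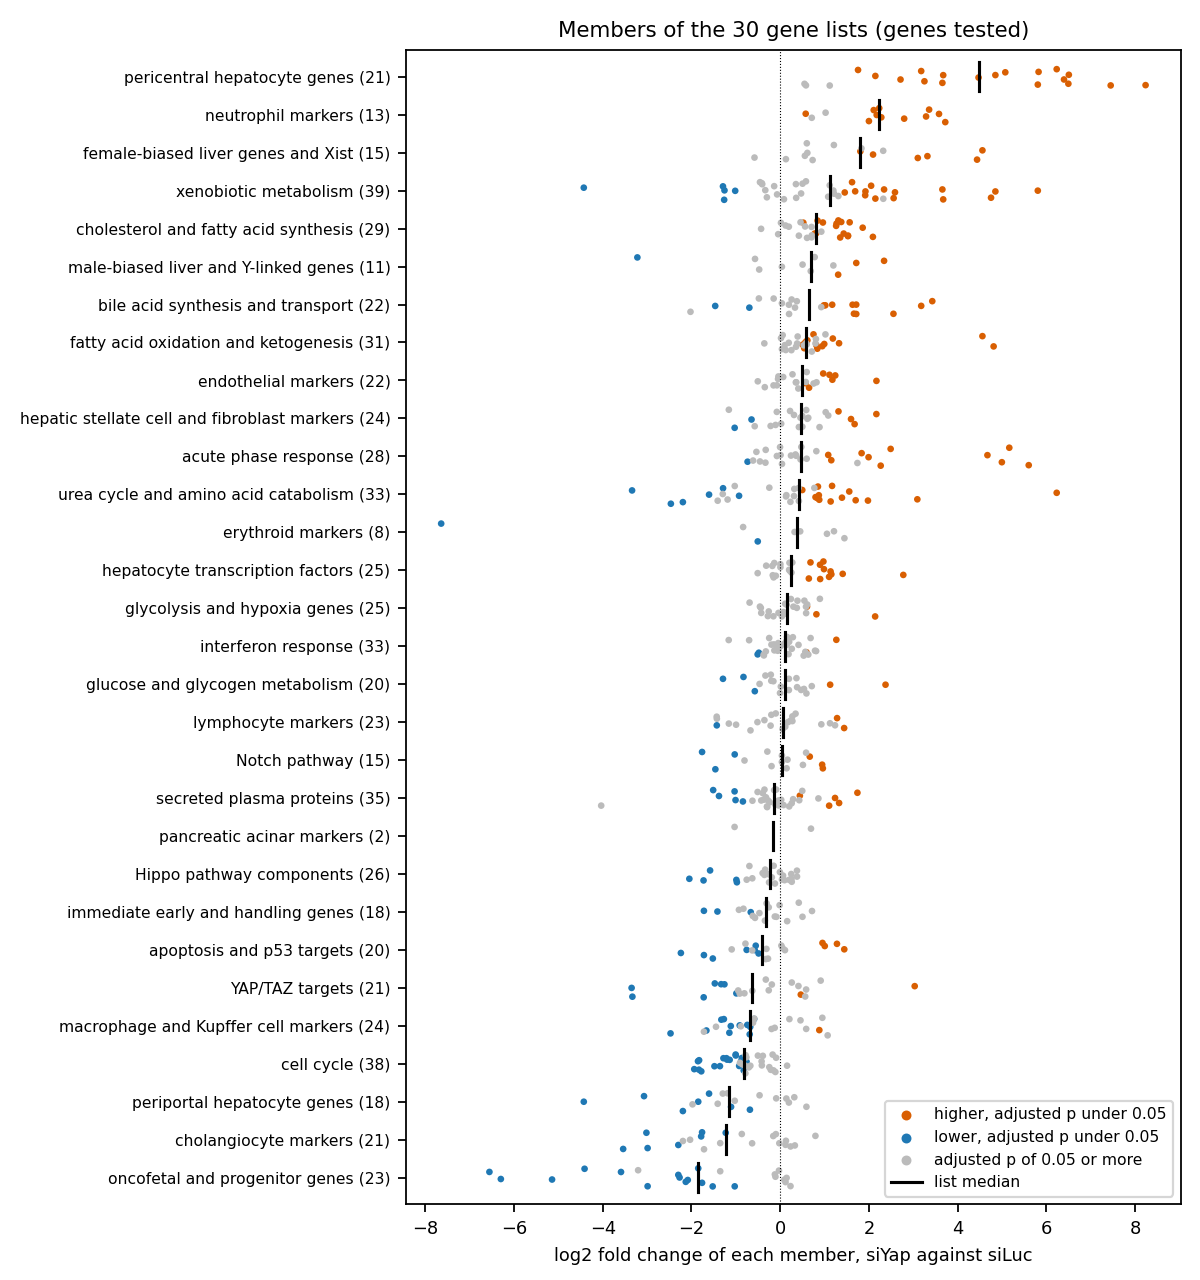
Log2 fold change of each tested member of the 30 lists (x axis, siYap against siLuc), with lists in rows ordered by their median (black tick) and the number of tested genes in brackets; orange and blue points are members higher and lower at an adjusted p under 0.05 over all genes, and grey points are not called. The pericentral list has the highest median (4.47) and the oncofetal and progenitor list the lowest (-1.85).

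Most neutrophil markers rose, and a minority of acute phase genes did. Of 13 neutrophil markers tested, 11 rose and none fell, 13 over the list alone, with a median log2 fold change of 2.23. The granule proteins Ltf and Mpo rose from 2.02 ± 1.42 to 18.2 ± 14.3 FPKM and from 0.319 ± 0.305 to 4.02 ± 4.34 FPKM, and Mmp9 from 0.269 ± 0.091 to 1.14 ± 0.786 FPKM. Without siYap replicate 1 the log2 fold changes of Ltf and Mpo went from 3.29 to 2.63 and from 3.72 to 2.72. Camera called the list higher (adjusted p = 1.27e-05, and 0.539 with an estimated correlation). In the acute phase list, 10 of 28 rose and 1 fell, 11 and 1 over the list alone. Serum amyloid Saa3 rose from 12.4 ± 10.1 to 601 ± 479 FPKM (log2 fold change 5.60 ± 0.64, adjusted p = 4.55e-05), and Saa1, which has a near-identical neighbour in Saa2, from 43.6 ± 30.2 to 1309 ± 1185 FPKM. This list was called higher (adjusted p = 0.0295, and 0.698 with an estimated correlation), but not without siLuc replicate 7 (adjusted p = 0.0544), siYap replicate 1 (0.0962) or siYap replicate 5 (0.175), nor with the first digit of the file code as a term (0.131), with the replicate number as a block (0.1015) or in fry (0.0855). Interferon response genes were not called as a list (adjusted p = 0.770), with 2 of 33 genes higher and 2 lower over all genes and none over the list alone.

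Markers of other cells moved in different directions. Of 24 macrophage and Kupffer cell markers, 11 fell and 1 rose, 12 and 2 over the list alone. Lyz2, whose reads may be split with its copy Lyz1, fell from 768 ± 246 to 304 ± 88.1 FPKM, Emr1, the F4/80 antigen, from 29.8 ± 8.04 to 13.04 ± 4.59 FPKM, and the complement subunit C1qa from 106 ± 25.1 to 54.3 ± 12.2 FPKM. The list was called lower (adjusted p = 0.0303, and 0.547 with an estimated correlation), but not without siYap replicate 2 (0.0733) or siYap replicate 5 (0.0938), nor with the digit of the file code as a term (0.0625). Endothelial markers rose in 7 of 22 genes and fell in none, and over the list alone 10 rose and 1 fell. Esam rose from 4.003 ± 0.903 to 8.95 ± 2.14 FPKM and Eng, endoglin, from 2.98 ± 0.864 to 6.71 ± 2.12 FPKM. The endothelial list was called higher (adjusted p = 0.0198, and 0.539 with an estimated correlation), but not without siYap replicate 1 (0.0529). Stellate cell and fibroblast markers were not called (adjusted p = 0.370), with 4 of 24 higher and 2 lower, 3 and 1 over the list alone. The collagen Col1a1 rose from 1.57 ± 0.746 to 6.75 ± 4.62 FPKM, a call that ended without siYap replicates 1 and 3 together (adjusted p = 0.0565), and Fbln2 fell from 2.58 ± 0.670 to 1.54 ± 0.340 FPKM. Lymphocyte markers were not called (adjusted p = 0.770), with 2 of 23 higher and 1 lower, 1 and 0 over the list alone, and their median (0.05) and mean (-0.04) log2 fold change differed in sign. The granzyme Gzma rose from 1.88 ± 0.644 to 4.60 ± 1.65 FPKM. Erythroid (adjusted p = 0.651, 0 of 8 higher and 2 lower) and pancreatic acinar markers (adjusted p = 0.890, none of the 2 tested called) were not called either. Over the list alone 1 erythroid gene was higher and 2 were lower, and no acinar gene was called. Camera ranked both lists as higher, while the mean log2 fold change was -0.56 for erythroid and -0.17 for acinar markers and the erythroid median was 0.39.

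Immediate early genes, which respond to handling of tissue, were not called as a list (adjusted p = 0.166). Of 18, 3 fell and none rose, also over the list alone. Fos fell from 3.43 ± 0.952 to 1.23 ± 0.434 FPKM and Junb from 15.03 ± 3.03 to 9.66 ± 1.82 FPKM. Among female-biased liver genes, 6 of 15 rose and none fell, 7 over the list alone. Cyp2c69 rose from 0.266 ± 0.127 to 5.94 ± 4.76 FPKM. The list was called higher (adjusted p = 0.00139, and 0.539 with an estimated correlation), and stayed called with sex as a term (0.00127) and without any 1 library (highest adjusted p 0.00455). Among male-biased and Y-linked genes, 3 of 11 rose and 1 fell, also over the list alone, and the list was not called (adjusted p = 0.102). Cyp2d9, a male-biased cytochrome, rose from 18.6 ± 9.03 to 93.96 ± 43.0 FPKM. With sex as a term in the model, 4275 genes were called. Of 107 genes checked, which include those named here, 102 had a difference of the same sign within each of the 3 digits of the file code, and the exceptions were Stk3, Stk4, Ctgf, Epcam and Lipn. Most of these genes were chosen for their difference in the same libraries, so this count is no test of the digit. Lists held their sign in 19 of 30 cases.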

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

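The tests of explanations in this part, the counts of splits of the libraries included, were set down only after the results were seen. A library was taken as standing apart where its gap to the nearest library, over the range of its group, passed Dixon's 95% critical value, on log2 CPM for genes (levels are given in FPKM) and on the plain scale for library measures. This was tried in 226 groups of values, 107 genes and 6 library measures in each treatment, and 17 passed. Chance alone flags about 1 in 20.

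siYap replicate 1 was the lowest siYap library for Glul (1022 FPKM against 3961 to 6120 in the other siYap libraries), Etfa (113 against 212 to 247), AW549542 (1.47 against 14.1 to 29.7) and Pkp1 (0.310 against 2.19 to 2.46), and the highest for Fos (1.97 against 0.887 to 1.18). siYap replicate 2 was the highest for Ajuba (5.36 against 3.61 to 3.88) and the lowest for Lipn (0 against 0.0214 to 0.0238). siYap replicate 3 was the highest for Prss37 (0.0365) and Olfr153 (0.0428), both being at 0 in the other siYap libraries. For Prss37, Olfr153 and Lipn in siYap this is 1 fragment against 0, which counting alone gives. In siLuc, replicate 1 was the lowest for Tead4 (1.48 against 3.15 to 4.66), Spp1 (1912 against 3284 to 5012) and Stk4 (0 against 0.0456 to 0.0891), and the highest for Hsd17b13 (1006 against 294 to 477). siLuc replicate 2 was the lowest for Tff3 (15.2 against 476 to 1873). siLuc replicate 4 was the highest for Oat (149 against 11.9 to 35.6) and the lowest for Olfr153 (0.0335 against 0.665 to 1.89). siLuc replicate 8, the male library, was the lowest for Xist (10.6 CPM against 1179 to 2167).

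The pericentral genes were weighed first. Non-tumour liver taken with the siYap tumours would bring periportal transcripts as well, and the median of the periportal list was -1.15 on the log2 scale, with 0 of 18 members higher, which argues against mixed-in liver, although tissue from around central veins alone stays open. A batch marked by the file code is argued against by the differences within its digits, of which the lowest was 4.49. A chance assignment of tumours of another class to siYap gave an exact p of 0.0179 over the 56 splits of the file-name numbers, if these are independent units. This is the smallest p that these splits can give, and adjusted over the lists it was 0.0595. Such an assignment therefore stays open. The knockdown of Yap1 stays open as the explanation that the design names, and it may act on tumour cells or through which tumour cells survive.

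The list calls of neutrophil and acute phase genes were weighed next. More blood in the siYap samples would raise lymphocyte markers as well, but their median log2 fold change was 0.0542 against 2.23 for neutrophil markers. A single library does not account for the neutrophil call, whose highest adjusted p without any 1 library was 7.95e-05. For acute phase genes, camera's call ended with the digit of the file code as a term (adjusted p = 0.131), for a reason that was not tested. The difference in the mean of the list was 1.04 ± 0.33 (SE) without and 0.96 ± 0.35 with the digit, and it was above 0 within each digit (0.22 to 2.75). An exact permutation within the digits gave p = 0.0397 (0.0744 adjusted over the 30 lists). It does not pass over the lists and takes libraries that share a file-name number as independent. It therefore cannot decide whether batches are the cause. A response to the loss of Yap1 and a response to dying tumour cells were not tested.

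The number of changed genes was weighed against the quality of siYap replicates 1 and 3. Without both, 2984 genes were called. The 3 other pairs of siYap libraries that include replicate 3 gave 2428 to 2551 when left out, the 6 pairs without replicate 3 gave 3407 to 4310, and the 3 pairs with neither replicate 1 nor 3 gave 4133 to 4310. The count thus leaned on replicate 3, and whether its quality or its biology is the reason stays open.

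Other splits of the libraries were counted for the changed genes and for the lists. Of 100 splits of the 13 libraries, 1 (the real one) called as many as 4668 genes, and the highest of the others, in which siLuc replicate 4 took the place of siYap replicate 1, called 686. Of the 56 splits of the file-name numbers, 1 (the real one) called as many as 3793 in edgeR and the others called 0. Chance can be excluded for both counts only if the units that were split are independent, which the labels do not say. The share over the numbers, 1 of 56, is the smallest possible. For camera's p of the pericentral list, 2 of the 100 library splits were as small (real p 2.44e-18, smallest other 2.80e-19). Chance can be excluded over the libraries only if these are independent. Over the numbers it was 1 of the 56 splits (real p 1.36e-15, smallest other 4.11e-13), the smallest share possible. The exact permutation test of the list's mean gave p = 0.0179 over the numbers, and 0.0595 adjusted over the lists. Over the numbers, chance can thus be excluded only for this list taken alone, and only if the numbers are independent. For the oncofetal list chance can be excluded over the libraries only if these are independent (3 of 100, real p 5.97e-07, smallest other 4.40e-08). Over the numbers it cannot be excluded (4 of 56, real p 9.46e-06, smallest other 2.38e-08). These shares are not adjusted for the number of tests. Exact permutation tests of the oncofetal mean gave the smallest p they can give, 0.000777 over the libraries and 0.0179 over the numbers. Adjusted over the lists, these were 0.00777 and 0.0595. Over the numbers, 0.0595 was the lowest adjusted p of any list. Lists with large and small differences shared it, such as the pericentral (4.49) and the Hippo list (-0.39). The test over the numbers therefore does not pass, but with 56 splits this does not speak against a list.

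Chance cannot be excluded by camera's p for the YAP/TAZ target list (18 of 100, real p 0.0419, smallest other 0.00124, and 6 of 56, real p 0.0219, smallest other 0.00369) or the cell cycle list (19 of 100, real p 9.97e-08, smallest other 1.08e-26, and 8 of 56, real p 3.69e-12, smallest other 1.09e-18). Camera compares a list with other genes, and the exact permutation tests of the same lists' means, which do not, gave smaller shares (p of 0.00466 and 0.0194 over the libraries). For the number of hepatocyte lists called higher, 15 of 100 and 6 of 56 splits gave at least 4, with up to 6 and 7 in other splits, and chance cannot be excluded.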

How the results depend on the processing

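Yap1 stayed called in every alternative, with log2 fold changes between -1.69 and -1.47 when 1 library was left out. The count of changed genes (4668, 2422 higher and 2246 lower) lay between 3325 and 4633 without 1 library (1729 to 2397 higher, 1596 to 2236 lower), the lowest without siYap replicate 3. It became 2984 (1512 higher, 1472 lower) without siYap replicates 1 and 3 together, chosen after seeing the data, 2362 (1264 and 1098) at an adjusted p under 0.01, and 1992 (1053 and 939) with a log2 fold change of at least 1. The last 2 follow from a stricter threshold. The first leaned on replicate 3, as the pairs of siYap libraries left out show, and whether its quality or its biology is the reason stays open. With the replicate number as a block it was 2325 (1199 and 1126). The block leaves 4 residual degrees of freedom, and the numbers do not pair the libraries, since same-numbered libraries deviated with correlations of -0.12, 0.13, 0.07, 0.12 and -0.09 and only replicate 4 correlated best with its own number. The block ended 2 list calls and 18 calls of named genes.

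The YAP/TAZ target list (adjusted p = 0.0702) passed with counts summed per file-name number (0.0411), without a filter (0.0441), without siYap replicates 1 and 3 together (0.0245) and in fry (0.0116), and ranged from 0.0364 to 0.175 without 1 library. With an estimated correlation, the adjusted p was 0.362 for the oncofetal and the pericentral list and 0.539 for the cell cycle list, and 0 of the 7 hepatocyte lists were called against 4. The estimated correlations were 0.157, 0.524 and 0.636 for these 3 lists and 0.0614 to 0.485 for the 4 hepatocyte lists, against the preset 0.01. A higher correlation between members raises camera's p, so the p-values at the preset rest on a far lower one. Why members varied together was not tested. Of the 16 list calls, 11 held in all alternatives but the estimated correlation. Of 130 called named genes among 140, 103 kept their call in every alternative that gave a value. Among the genes chosen after their values were seen, no sign changed. Stk4, near 0 throughout, changed sign with the file-name number as a random effect (0.061, adjusted p = 0.955). Hcrtr2 had at most 3 fragments in each siLuc library and Prss37 at most 1 in each siYap library, so that their fold changes are imprecise.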

Other observations

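The tests of the 3 lists in this part (Wnt feedback, clock and imprinted genes) and the genes named here were chosen after the results were seen. Genes of Wnt signalling and its feedback, apart from those in the lists above, moved in both directions. The intracellular inhibitor Nkd1 stood at 0.193 ± 0.059 FPKM (SD, n = 8) in siLuc and 5.18 ± 4.61 FPKM (SD, n = 5) in siYap tumours (log2 fold change 4.74 ± 0.46, adjusted p = 1.05e-05), the ubiquitin ligase Znrf3 at 2.31 ± 0.269 and 8.49 ± 3.17 FPKM (adjusted p = 5.99e-06), and the transcription factor Tcf7 at 0.473 ± 0.215 and 3.60 ± 1.79 FPKM (adjusted p = 2.55e-05). Each lay higher in all 5 siYap libraries than in any siLuc library. Of 12 such genes without Notum and Sp5, 6 rose and 2 fell. The falls were in the inhibitor Nkd2, from 0.863 ± 0.464 to 0.352 ± 0.122 FPKM (adjusted p = 0.0256, but 0.0599 without siYap replicate 2, 0.0549 without siYap replicate 4 and 0.0553 with the digit of the file code as a term), and in the receptor Fzd5, from 4.78 ± 1.69 to 2.17 ± 0.674 FPKM (adjusted p = 0.00239). A candidate explanation is higher Wnt signalling in the siYap tumours, which stays open: camera gave p = 0.0444 for the 12 genes with the preset correlation and 0.0930 with an estimated one. That both should pass was required only after these values were seen. The list as first written also held Notum and Sp5, already chosen for their rise, and so gives no independent test. Transcript levels do not show where in the pathway a change would lie. Of 17 imprinted genes, 6 rose and 5 fell (camera adjusted p = 0.914, and 0.937 with an estimated correlation).

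Levels of the clock genes Arntl and Dbp are given by the first digit of the file code, whose effect was not tested. Arntl stood at 9.21 and 9.59 FPKM in the siLuc libraries with digit 6, at 3.35 FPKM in the one with digit 8, and between 0.305 and 0.601 FPKM in the 5 with digit 7. In siYap libraries it was 1.48 and 2.59 FPKM with digit 6, 1.115 FPKM with digit 8, and 0.385 and 0.424 FPKM with digit 7. Dbp, which peaks when Arntl is low, was between 12.1 and 19.02 FPKM in siLuc libraries with digit 7, at 4.18 and 4.78 FPKM in those with digit 6 and at 3.20 FPKM in the one with digit 8. In siYap libraries it was 16.3 and 23.0 FPKM with digit 7, 8.98 and 9.46 FPKM with digit 6 and 13.1 FPKM with digit 8. Without a term for the digit, neither gene was called between treatments by edgeR (adjusted p = 0.311 and 0.577). With the digit as a term both were, Arntl lower (log2 fold change -1.16, adjusted p = 0.0122) and Dbp higher (0.90, adjusted p = 0.00852). Of 16 clock genes, 3 rose and none fell (camera adjusted p = 0.0492 over the 3 lists, 0.00544 with the digit as a term and 0.3001 with an estimated correlation). Clock genes can peak at opposite times, as Arntl and Dbp do. A test for a shared direction therefore cannot decide on a shift of the clock.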
